A study of Mus musculus with 5 samples.

How the data were processed

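Sciatic nerves of mouse pups at postnatal day 2 were excised and pooled by genotype, with 12 nerves in each pool, per the labels' protocols. The labels give 3 pools of wild-type nerves (WT pools 1, 9 and 11) and 2 pools of Ebf2-/- nerves (KO pools 2 and 4), all on a C57Bl6N background. Pups came from crosses of heterozygous parents. Total RNA was extracted with a silica column kit, and biotin-labelled cDNA was hybridised to Affymetrix whole-transcript arrays, 1 array per pool, per the labels' protocols. The labels do not give the number of animals or litters behind a pool, the hybridisation dates or the part of Ebf2 that the allele lacks.

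The deposited values are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of a probe set by median polish. Its version and settings are not given in the sources used here. The deposited table held 10361 probe sets on 5 arrays, with log2 values from 2.84 to 14.3. The medians of the 5 arrays were 9.11, 9.09 and 9.04 for WT pools 1, 9 and 11 and 9.11 and 8.93 for KO pools 2 and 4, so the distributions were not equal in the table as used here. In 27% of the probe sets at least 1 pair of arrays shared the same value, as a summary by median polish can give.

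The spread of the values had a lower bound. In all probe sets of the table the fourth-ranked of the 5 values exceeded the lowest by at least 0.175 on the log2 scale, and in 1134 of them this gap was below 0.2. A filter on the spread between arrays leaves such a lower bound, and no such filter is stated in the sources used here. Genes with little spread between the pools are not analysed here, and Ngfr and Actb are among the genes not analysed. The bound also keeps a gene that is low on 1 array and drops one that is high on only 1. A filter of this kind removes the small variances from which limma estimates the common variance. It was tested on simulated data without any change, with 20722 features, an assumed prior of 4 degrees of freedom and an assumed standard deviation (SD) of 0.13. The filter kept 13463 to 13723 of them, more than the 10361 probe sets of the table, and raised the median estimate of the prior degrees of freedom from 4 to 20, and calls at adjusted p below 0.05 appeared in 20 of 20 filtered runs (median 17, highest 29) against 1 of 20 unfiltered runs. These counts depend on the assumed settings.

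Probe sets were named through the platform annotation dated 2016. Of the 10361 probe sets, 9411 had 1 gene symbol, 384 had several and 566 were not listed. Symbols were compared with RefSeq genes of assembly GRCm38.p6 through their gene identifiers, and 0 symbols had to be updated. No probe set with several symbols was named. The 9407 symbols included 4 with several probe sets, each of which was represented by its probe set with the highest mean over the 5 arrays. The build behind the array design is not given in the sources used here, so no coordinates are reported, and the reference served only for names and for the order of genes along chromosomes.

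The genotypes were compared on the deposited log2 values as they stand with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with the default prior and no covariates. P-values were two-sided and adjusted by Benjamini-Hochberg over all 10361 probe sets, and a probe set was called at adjusted p below 0.05. The fit had 3 residual and 17.4 prior degrees of freedom. A log2 fold change is the mean of the KO pools minus the mean of the WT pools, and its standard error (SE) is the moderated one. The number of arrays (3 against 2) limits the precision. P-values measure only the spread between these pools, which may be technical in part. A looser count used unadjusted p below 0.05 with a change of at least 1.5-fold.

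On simulated data with 200 changed probe sets in each of 10 runs over 10361 probe sets, the same fit recovered 30.6% of the probe sets changed by 0.585 on the log2 scale, 95.2% of those changed by 1, and 100% of those changed by 1.5 or 2. In these runs 4.1% of the calls were false. The variances were drawn from the prior fitted to the table, which a filter may have raised, with independent noise and no filter or structure of pools. The simulated data thus met the assumptions of the fit. The recovery and the share of false calls are best cases and do not contain the effect of the filter.

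Before the data were examined, 32 gene lists were fixed for Schwann cells, lipid synthesis, signalling and the other cell types that a dissected nerve can hold. A list was tested where at least 5 members were measured, which held for 31 lists. The sex-linked list had 4 measured members and was not tested. The main test was camera in limma with a preset correlation of 0.01 between genes, two-sided, adjusted over the 31 lists. Beside it stand camera with a correlation estimated for each list, and fry. The directional p of fry asks whether the genes of a list move, on balance, one way. With an estimated correlation camera uses the 3 residual degrees of freedom, so its p-values rise even where genes are not correlated. The mast cell list, with an estimated correlation of -0.014, went from unadjusted camera p = 0.0173 to 0.0897. A list that fails there may thus fail for lack of degrees of freedom. The adjustment also gave many lists the same adjusted p of 0.454. Counts of changed members were made over all probe sets and again adjusted over the list alone.

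The rule for named genes was also fixed before the data were examined. It took, in each direction, up to 12 genes with 1 symbol, adjusted p below 0.05 and no overlap between the 3 WT and the 2 KO values, by the size of the log2 fold change. It also took Ebf1 to Ebf4 and, of each fixed list, up to 6 members past adjusted p below 0.05 and up to 4 others by the size of the log2 fold change. Genes named outside this rule are said to have been chosen after their values were seen.

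The alternatives tried were leaving out each pool in turn, quantile normalisation, centring each array on its median, filters at the 25th and 50th percentiles of mean signal, a trended and robust prior, array weights, an ordinary test per probe set without moderation, another threshold, the mean over the probe sets of a gene, and for the lists other tests and members. A fit with WT pools 9 and 11 as a block and a fit without these pools were added after the data were seen. In both, the genotypes are compared through WT pool 1 alone, which has no second pool beside it. WT pool 1 also had the lowest Y-linked levels of the 5 pools, so these fits do not separate genotype from sex. Lists were tested in these fits only by camera with the preset correlation, which takes genes as nearly independent. A list that passes there is thus no evidence across WT pools. Pool numbers are not shared between the genotypes and were not used as pairs.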

Results

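Ebf2 encodes a transcription factor of the early B cell factor family. The design compared the RNA of sciatic nerves from Ebf2-/- and wild-type mouse pups at postnatal day 2, when Schwann cells are starting to form myelin, and asked which genes differ between the genotypes. Each array measured 1 pool of 12 nerves, with 3 wild-type (WT) and 2 Ebf2-/- (KO) pools. All levels are log2 values, and each log2 fold change is KO minus WT with its standard error (SE), from 3 WT and 2 KO pools. Adjusted p-values are from limma.

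Ebf2 itself fell in the KO pools. Its mean log2 level was 11.36 ± 0.21 (SD, n = 3) in WT and 9.00 ± 0.35 (SD, n = 2) in KO, a 5.16-fold lower level (log2 fold change -2.37, SE 0.19, adjusted p = 4.97e-07). The probe set (10416126) read 11.55, 11.14 and 11.40 in WT pools 1, 9 and 11 and 9.25 and 8.74 in KO pools 2 and 4, so all 5 arrays stood on the side of their label. The labels do not say which exons are missing, so the signal left in the KO pools cannot be assigned to a part of the transcript. Ebf1, a close relative that binds the same DNA motif, rose 1.68-fold (log2 fold change 0.75, SE 0.17, adjusted p = 0.0445). Ebf3, another member of the family, had a log2 fold change of 0.64 (SE 0.18), or 0.37 against WT pool 1 alone, and did not pass (adjusted p = 0.0933), and Ebf4 was not analysed here. In the list of early B cell factors and their zinc finger partners, 5 of 6 members were measured, 1 rose (Ebf1), 1 fell (Ebf2) and 3 did not pass, against 2 risen and 1 fallen when adjusted over the list alone. As a group this list did not pass (camera adjusted p = 0.575), with a positive median (0.25, and 0.15 without WT pool 11) and a negative mean (-0.12). The Ebf2 difference no longer passed without WT pool 1 (adjusted p = 0.0657), KO pool 2 (0.119) or KO pool 4 (0.782), with log2 fold changes of -2.27, -2.62 and -2.12. It was -2.56 against WT pool 1 alone (adjusted p = 0.839 with pools 9 and 11 as a block and 0.857 without them).

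Kera, Pi15 and Epyc led the rises in the KO pools. Kera, which encodes the small leucine-rich proteoglycan keratocan, rose 3.97-fold (log2 fold change 1.99, SE 0.22, adjusted p = 5.00e-05). Pi15, a secreted protein of the CAP family, rose 3.54-fold (1.82, SE 0.22), and Epyc, for epiphycan, a proteoglycan related to keratocan, rose 3.49-fold (1.80, SE 0.21). Gcg, which encodes the precursor of glucagon, rose 3.07-fold (1.62, SE 0.20), and Moxd1, a monooxygenase related to dopamine beta-hydroxylase, rose 3.06-fold (1.62, SE 0.20). Aldh1a2, an enzyme that makes retinoic acid, rose 2.83-fold (SE 0.19 on the log2 scale, adjusted p = 0.000182). The other 6 of the 12 largest rises were Raet1d, a ligand of the natural killer receptor NKG2D (1.43, SE 0.30), the ephrin receptor gene Epha3 (1.35, SE 0.26), Lgi2 (1.22, SE 0.21), Nell1 (1.13, SE 0.19), the LIM-domain gene Fhl2 (1.11, SE 0.22) and Glt8d2 (1.10, SE 0.18). Against WT pool 1 alone the rises were 0.47 for Raet1d, 0.57 for Epha3, 0.67 for Lgi2 and 0.55 for Fhl2, which was over 1.5 times smaller.

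Next to Ebf2, the falls were led by Pmp2 and included Egr2. Pmp2, the fatty acid-binding protein of peripheral myelin, fell to a 4.42-fold lower level (log2 fold change -2.14, SE 0.29, adjusted p = 0.000407). Egr2, the zinc finger transcription factor required for peripheral myelination, went from 11.37 ± 0.17 (SD, n = 3) in WT to 10.24 ± 0.68 (SD, n = 2) in KO (log2 fold change -1.13, SE 0.22, adjusted p = 0.0181). Cldn19, a tight junction protein of Schwann cells, fell as well (log2 fold change -1.11, SE 0.20), as did Dusp15, a phosphatase gene (-1.32, SE 0.21), and Elovl7, which lengthens fatty acids (-1.05, SE 0.19). The other falls among the 12 largest, Ebf2 aside, were the sodium-proton exchanger gene Slc9a3 (-1.36, SE 0.30), the microRNA gene Mir379 (-1.24, SE 0.24), the natural killer receptor gene Klrb1a (-1.18, SE 0.24), Rasgef1a (-1.18, SE 0.23), Shtn1, which encodes shootin-1 of growing axons (-1.17, SE 0.27), and the vault RNA gene Vaultrc5 (-1.13, SE 0.21). The KO pools differed most from each other at Slc9a3 (SD 1.20), Shtn1 (SD 1.04) and Pmp2 (SD 1.02) among these genes. Without KO pool 4 the log2 fold changes were -1.42 for Pmp2, -0.65 for Egr2, -0.51 for Slc9a3, -0.74 for Mir379, -0.70 for Klrb1a, -0.77 for Rasgef1a and -0.44 for Shtn1. Vaultrc5 was at -0.64 against WT pool 1 alone.

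**Figure D1:**
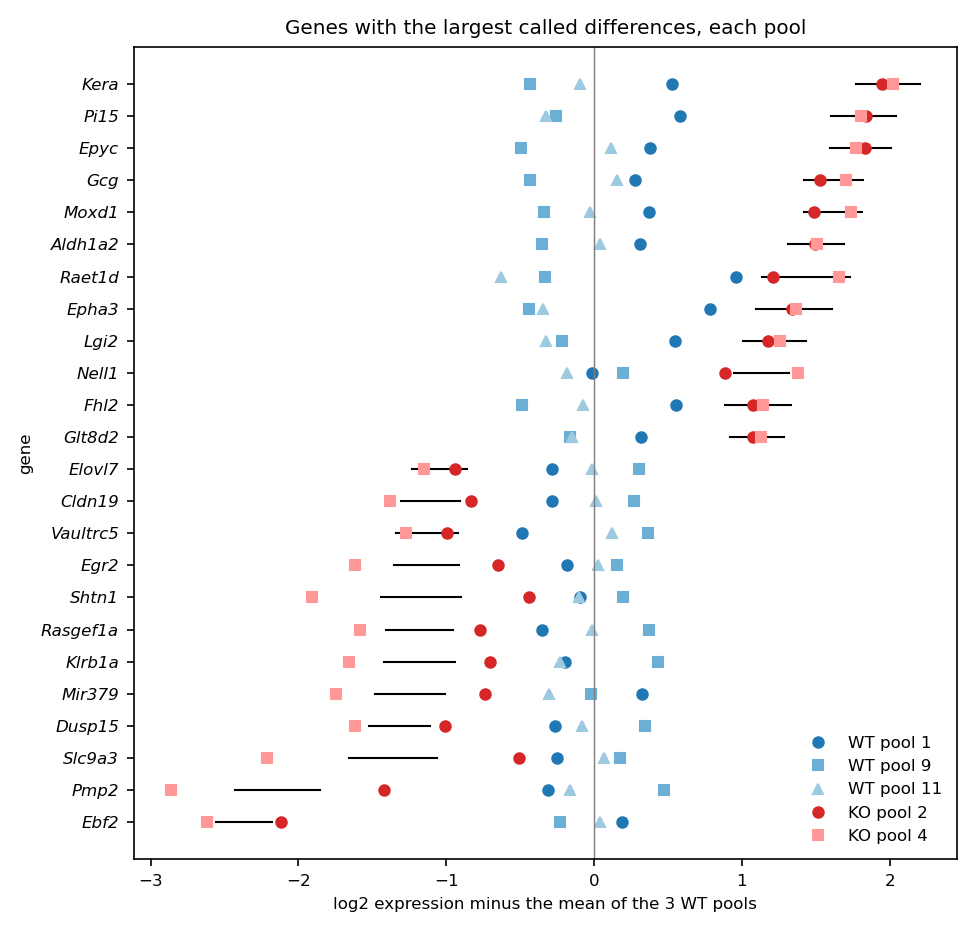
Log2 level of each pool minus the mean of the 3 WT pools (horizontal axis) for the 12 largest called rises and falls, 1 point per pool, with a black line that spans 1 SE on either side of the log2 fold change. The KO pools (red) lie apart from the WT pools (blue) in all genes shown, as the rule for choosing them requires, from Ebf2 (-2.37) to Kera (1.99).

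In all, 70 probe sets passed adjusted p below 0.05, 36 higher and 34 lower in KO, and 65 of them stood for genes with 1 symbol, 32 higher and 33 lower. At unadjusted p below 0.05 there were 1483 probe sets, while other splits of the 5 pools into 3 and 2 gave from 36 to 1771, the highest with WT pools 9 and 11 against the rest. Of the genes, 455 passed unadjusted p with at least 1.5-fold, 215 higher and 240 lower. These counts were 300 higher and 141 lower after centring each array on its median. The number of calls rested on the prior, which a filter on spread raises, and the table has the lower bound on spread that such a filter leaves. Simulated data with no change and such a filter gave a median of 17 calls and up to 29 under assumed settings, which kept 13463 to 13723 of 20722 features and so do not match the 10361 probe sets of the table. A test without moderation called 0 probe sets (498 at unadjusted p below 0.05), median centring and quantile normalisation called 1 each, Ebf2, and 0 were called without either KO pool or against WT pool 1 alone. The median absolute log2 fold change of the 65 genes was 0.99, and 0.75 against WT pool 1 alone. Of the 33 genes called lower, 31 were further down in KO pool 4 than in KO pool 2. Of the 32 called higher, 24 were further up in KO pool 4. KO pool 4 also had the lowest array median (8.93).

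Myelin genes lay lower in the KO pools as a group. Of the 21 genes fixed for compact myelin and Schwann cell membrane proteins, 15 were measured, 5 fell, 0 rose and 10 did not pass, and 7 fell when adjusted over the list alone. Besides Pmp2 and Cldn19, the falls were Gldn, for gliomedin of the node of Ranvier (log2 fold change -1.02, SE 0.20), Mag, for the myelin-associated glycoprotein (-0.99, SE 0.19), and Ncmap, for a protein of noncompact myelin (-0.86, SE 0.19), at -0.55 against WT pool 1 alone. Mbp, for myelin basic protein, and Cnp, both chosen after their values were seen, were at -0.24 (SE 0.17) and -0.23 (SE 0.17), and neither passed. Another 6 genes of the list were not analysed here, so the counts cover part of the list, and a filter on spread would leave out the genes that differ least. With 13 of 15 members lower and a median of -0.37, the list passed camera (adjusted p = 5.88e-09). It did not pass with an estimated correlation (0.411, adjusted p = 0.454, unadjusted p = 0.0821 on 3 degrees of freedom) or with fry (adjusted p = 0.238). Its median was -0.23 against WT pool 1 alone, where camera was run only with the preset correlation. Genes of skin and muscle also lay higher in WT pools 9 and 11 than in the other pools. The myelin list lay higher there by a median of 0.41, but the other pools include both KO pools. Its mean was 10.695, 11.034 and 10.802 in WT pools 1, 9 and 11. In KO pools 2 and 4 it was 10.366 and 10.157.

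Transcription factors of myelination had Egr2 as their 1 fall among 11 measured genes, 10 of which did not pass, with 1 fall when adjusted over the list alone as well. Pou3f1, which precedes Egr2 in the promyelinating stage, was at -0.43 (SE 0.18), or -0.19 without KO pool 4, and Sox10, which marks the Schwann lineage and was chosen after its value was seen, at -0.20 (SE 0.17), and neither passed. Sox10 read 11.64 in KO pool 2 and 11.24 in KO pool 4 against a WT mean of 11.65, so its difference came from KO pool 4 alone. The list lay lower (median -0.20, camera adjusted p = 0.0305), though with adjusted p = 0.505 with an estimated correlation. It averaged 11.13, 11.19 and 11.10 in WT pools 1, 9 and 11 and 11.06 and 10.75 in KO pools 2 and 4, with medians of -0.40 without KO pool 2 and -0.08 without KO pool 4. The list did not pass against WT pool 1 alone (camera adjusted p = 0.0660). Of 16 measured genes of immature and non-myelinating Schwann cells, 1 rose, Id3, an inhibitor of basic helix-loop-helix factors (log2 fold change 0.83, SE 0.18, adjusted p = 0.0380), and 15 did not pass. Adjusted over the list alone 3 rose and 1 fell. This list lay higher (median 0.18, or 0.10 without WT pool 9, camera adjusted p = 0.0297), with adjusted p = 0.454 with an estimated correlation, and did not pass against WT pool 1 alone (camera adjusted p = 0.414). Neither the 6 measured genes of repair Schwann cells (camera adjusted p = 0.967) nor the 9 of axon-glia signalling and Schwann cell receptors (camera adjusted p = 0.489) passed as a group, and 0 of their members changed over all genes or adjusted over the list alone.

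Lipid genes were tested as 2 lists. In fatty acid and glycosphingolipid synthesis 2 of 15 measured genes fell, over all genes and adjusted over the list alone: Elovl7 and Fa2h, which hydroxylates the fatty acids of myelin galactolipids (log2 fold change -0.79, SE 0.18, adjusted p = 0.0465). The other 13 did not pass, and the list itself did not pass (median -0.32, camera adjusted p = 0.0816), with medians of -0.41 without KO pool 2 and -0.11 without KO pool 4. The fatty acid and glycosphingolipid synthesis list passed in 4 of 18 alternatives, namely both fits against WT pool 1 alone (median -0.21, lowest camera adjusted p = 0.0309), quantile normalisation and the filter above the 50th percentile. In cholesterol biosynthesis 0 of 14 measured genes changed and 1 fell when adjusted over the list alone, with Idi1 at -0.86 (SE 0.21, adjusted p = 0.0614), or -0.43 against WT pool 1 alone. With 12 of 14 members lower the cholesterol list passed camera (median -0.29, adjusted p = 0.00408), and had adjusted p = 0.608 with an estimated correlation. Its shift depended on single pools, with a median of -0.10 without KO pool 2 and -0.46 without KO pool 4. The list averaged 10.03, 10.528 and 10.185 in WT pools 1, 9 and 11 and 9.826 and 10.137 in KO pools 2 and 4. It did not pass without KO pool 2 or without WT pool 9. The median against WT pool 1 alone was -0.10, and the list did not pass there.

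Connective tissue genes lay higher in the KO pools as groups, with few changed members, and the tendon list did so mainly through Kera. In the fibroblast and collagen matrix list 16 of 17 measured genes were higher, 0 passed over all genes and 2 rose when adjusted over the list alone (median 0.28, camera adjusted p = 8.84e-05, adjusted p = 0.454 with an estimated correlation). Of 10 measured perineurium genes 1 rose, Moxd1, and adjusted over the list alone 3 rose and 1 fell (median 0.24, camera adjusted p = 0.0279, adjusted p = 0.454 with an estimated correlation). Of 5 measured tendon genes 1 rose, Kera, over all genes and adjusted over the list alone (median 0.13, camera adjusted p = 0.0182, adjusted p = 0.454 with an estimated correlation). The tendon mean was 0.47, with Kera at 1.99 and the other members from -0.04 (Scx) to 0.22 (Fmod). A test of the tendon list without Kera was not run. All 10 measured genes of the insulin-like growth factor system were higher, 0 passed over all genes and 5 rose when adjusted over the list alone. Igfbp6, which binds IGF-2, was at 0.64 (SE 0.18, adjusted p = 0.105) and the list had a median of 0.39 (camera adjusted p = 3.58e-05, adjusted p = 0.454 with an estimated correlation). Of 8 measured Hedgehog pathway genes 7 were higher and 4 rose when adjusted over the list alone, but 0 over all genes (median 0.39, camera adjusted p = 0.00497, adjusted p = 0.454 with an estimated correlation). When compared with WT pool 1 alone, the fibroblast (0.13) and insulin-like growth factor (0.25) lists had smaller medians. They passed there, but with genes taken as nearly independent and WT pool 1 as the only reference. The Hedgehog (median 0.15), perineurium (0.15) and tendon (0.12) lists did not pass there. Without WT pool 9 the medians were 0.16 for perineurium and 0.08 for tendon, and neither passed. The 8 cartilage and bone genes did not pass as a group (camera adjusted p = 0.688), with 1 fall adjusted over the list alone, 0 over all genes, and a median of 0.01 beside a mean of -0.06.

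Lists of dividing and vascular cells lay higher in the KO pools with 0 members called. Of 33 measured cell cycle genes 32 were higher, led by Rrm2 at 0.73 (SE 0.21), or 0.38 against WT pool 1 alone, with 0 passing over all genes or adjusted over the list alone (median 0.43, camera adjusted p = 1.82e-10, adjusted p = 0.454 with an estimated correlation). Of 16 endothelial genes 15 were higher and 0 passed either way (median 0.42, camera adjusted p = 2.10e-05, adjusted p = 0.472 with an estimated correlation). Of 10 pericyte and smooth muscle genes 8 were higher, 0 passed over all genes and 4 rose when adjusted over the list alone, with Myh11, the smooth muscle myosin heavy chain, at 0.99 (SE 0.32), or 0.02 against WT pool 1 alone (median 0.54, or 0.35 without WT pool 11, camera adjusted p = 0.00241, adjusted p = 0.454 with an estimated correlation). Of 9 Notch target genes 8 were higher, 0 passed over all genes and 3 rose when adjusted over the list alone (median 0.30, camera adjusted p = 0.00497, adjusted p = 0.454 with an estimated correlation). Without KO pool 2 the Notch median was 0.07 (camera adjusted p = 0.316). These lists also differed between the WT pools. The cell cycle genes averaged 10.63 in WT pool 1, 10.12 and 10.01 in WT pools 9 and 11, and 10.67 and 10.63 in KO pools 2 and 4. Against WT pool 1 alone the medians were 0.05 for the cell cycle, 0.14 for endothelium and 0.10 for Notch targets, and the smooth muscle median was -0.0005, and none of these 4 lists passed there (lowest camera adjusted p = 0.204, with pools 9 and 11 as a block).

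Skin and muscle genes marked WT pools 9 and 11. The 10 keratinocyte genes averaged 7.40 in WT pool 1, 9.66 and 8.92 in WT pools 9 and 11, and 7.47 and 7.75 in KO pools 2 and 4. All 10 were lower in KO, 0 passed over all genes and 6 fell when adjusted over the list alone (median -0.76, camera adjusted p = 3.06e-06, adjusted p = 0.454 with an estimated correlation). The 27 skeletal muscle genes averaged 9.44, 10.80 and 10.66 in WT pools 1, 9 and 11 and 9.89 and 10.12 in KO pools 2 and 4. Of these 22 were lower in KO and 0 passed over all genes or adjusted over the list alone (median -0.33, camera adjusted p = 0.00497, adjusted p = 0.731 with an estimated correlation). Against WT pool 1 alone the skeletal muscle median turned to 0.55 and the keratinocyte median to 0.20. Brown adipocyte genes, all 7 of them lower with 0 passing either way, had a median of -0.36 (camera adjusted p = 0.0165, adjusted p = 0.455 with an estimated correlation) that turned to 0.11. Erythroid genes, 5 of 5 lower, with 0 passing over all genes and 1 fallen when adjusted over the list alone, had a median of -0.23 (camera adjusted p = 0.0355, adjusted p = 0.505 with an estimated correlation) that turned to 0.12. Without WT pool 9 alone the medians were -0.02 for skeletal muscle, -0.38 for keratinocyte, -0.16 for brown adipocyte and -0.06 for erythroid genes, of which the keratinocyte list passed (camera adjusted p = 0.0111).

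Of the remaining lists 3 passed camera, all higher in KO and with 0 members passing over all genes or adjusted over the list alone. Mast cell genes were higher in 8 of 9 cases (median 0.21, camera adjusted p = 0.0297, adjusted p = 0.454 with an estimated correlation), with the protease gene Cpa3 at 0.52 (SE 0.17). The mast cell list passed in only 2 of the 5 fits without 1 pool, and not without KO pool 2. It passed against WT pool 1 alone (median 0.25), but with genes taken as nearly independent and WT pool 1 as the only reference. Circadian clock genes were higher in 9 of 11 cases (median 0.33, camera adjusted p = 0.00548, adjusted p = 0.454 with an estimated correlation), but averaged 9.55 in KO pool 2 and 9.90 in KO pool 4 against 9.49, 9.16 and 9.58 in WT pools 1, 9 and 11. The clock median was 0.58 without KO pool 2 and 0.12 without KO pool 4 (camera adjusted p = 0.183), and the list did not pass against WT pool 1 alone (camera adjusted p = 0.172). Interferon response genes were higher in 10 of 11 cases (median 0.28, camera adjusted p = 0.00785, adjusted p = 0.481 with an estimated correlation), but averaged 8.72 in KO pool 2 and 7.97 in KO pool 4 against 8.16, 8.07 and 7.90 in WT pools 1, 9 and 11, and without KO pool 2 the median turned to -0.14. The interferon list did not pass against WT pool 1 alone (camera adjusted p = 0.204). Macrophage (camera adjusted p = 0.769), lymphocyte and granulocyte (0.145), white adipocyte (0.170), and neuron and axon genes (0.169) did not pass, and 0 of their members changed over all genes or adjusted over the list alone. The lymphocyte and granulocyte list had a median of 0.13 (0.02 without WT pool 1) and passed in 4 of 16 alternatives, namely both fits against WT pool 1 alone (median 0.35, lowest camera adjusted p = 8.69e-05), without WT pool 9, and with quantile normalisation. Neuron and axon genes and immediate early genes passed without WT pool 11 and white adipocyte genes without WT pool 1. Immediate early genes (0.145) and genes of the heat shock and unfolded protein response (0.789) did not pass either, with 0 members changed over all genes and 1 risen in each when adjusted over the list alone. The heat shock list had a median of -0.11, which turned to 0.03 without WT pool 9, and a mean of 0.03. The neuron and axon genes averaged 9.45 in WT pool 9 against 8.38 in WT pool 1. Over the 31 lists, 20 passed camera with the preset correlation, 13 higher and 7 lower. With an estimated correlation, on 3 residual degrees of freedom, 0 passed (0 at unadjusted p below 0.05). With fry 0 passed as well (4 at unadjusted p below 0.05). Of the 20 lists, 4 passed camera in each fit that left out 1 pool (myelin, cell cycle, fibroblast and collagen matrix, and insulin-like growth factor system) and 16 failed in at least 1 such fit. Without WT pool 1 the lists of myelination factors, perineurium, tendon, mast cells and the clock no longer passed. Without WT pool 9 this held for myelination factors, cholesterol, perineurium, tendon, skeletal muscle, brown adipocytes, erythroid cells and the clock, and without WT pool 11 for immature Schwann cells, mast cells, skeletal muscle and erythroid cells. Without KO pool 4 it held for myelination factors, Notch targets, perineurium, tendon, smooth muscle, erythroid cells and the clock. Without KO pool 2 the 4 lists above and the clock were the 5 that still passed.

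**Figure D2:**
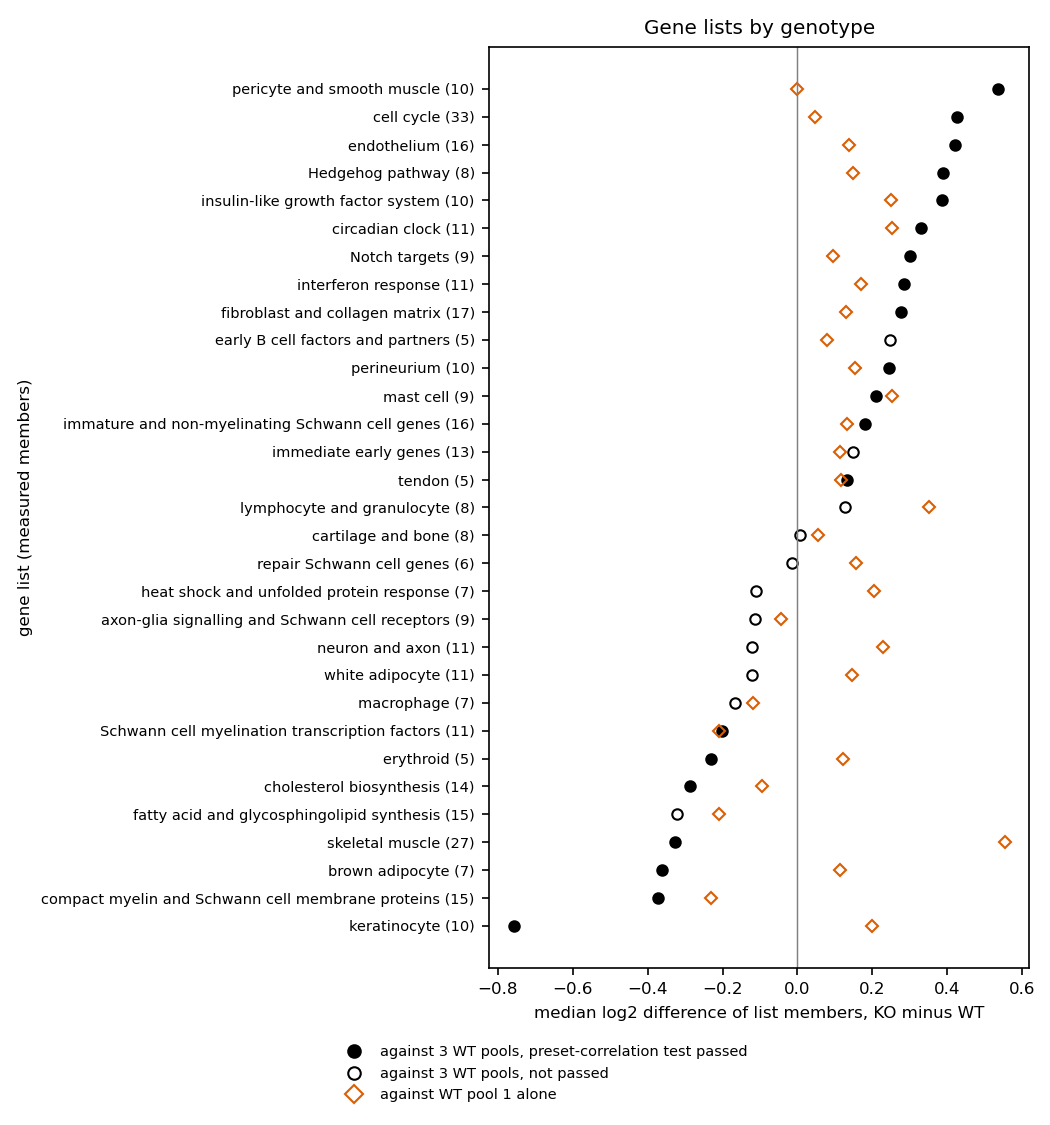
Median log2 difference, KO minus WT, over the measured members of each gene list (number in brackets). Circles compare 2 KO with 3 WT pools and are filled where camera with the preset correlation passed, and diamonds compare the KO pools with WT pool 1 alone. The skeletal muscle list moves from -0.33 to 0.55 and the myelin list from -0.37 to -0.23.

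The pools did not group by genotype alone. Over all probe sets the smallest difference between any 2 pools was between WT pool 1 and KO pool 2 (SD of the difference 0.203), followed by WT pools 9 and 11 (0.240), while WT pool 1 stood 0.374 from WT pool 9 and 0.319 from WT pool 11. The KO pools stood 0.344 apart. A comparison of WT pools 9 and 11 with the other 3 pools called 292 probe sets, 103 higher and 189 lower in these pools, of which 20 were also called between the genotypes. Among the sex-linked genes, Xist and the Y-linked Eif2s3y, Kdm5d and Uty were measured and 0 passed. Uty, chosen after its values were seen, read 5.76 in WT pool 1 and 8.33 and 7.95 in WT pools 9 and 11. It read 9.14 and 7.65 in KO pools 2 and 4. WT pool 1 was also the lowest at Eif2s3y (6.005) and Kdm5d (6.64) and the highest at Xist (13.11), as less male RNA in it would give. Comparisons with WT pool 1 alone thus do not separate genotype from the sex of the pups. In the main fit the log2 fold changes were 1.05 (SE 0.48) for Uty, 0.88 (SE 0.55) for Eif2s3y and 0.78 (SE 0.33) for Kdm5d. Xist was at -0.50 (SE 0.20). KO pool 2 was the highest at each Y-linked gene, while KO pool 4 lay below WT pools 9 and 11. The main comparison is thus not free of a difference in sex either.

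**Figure D3:**
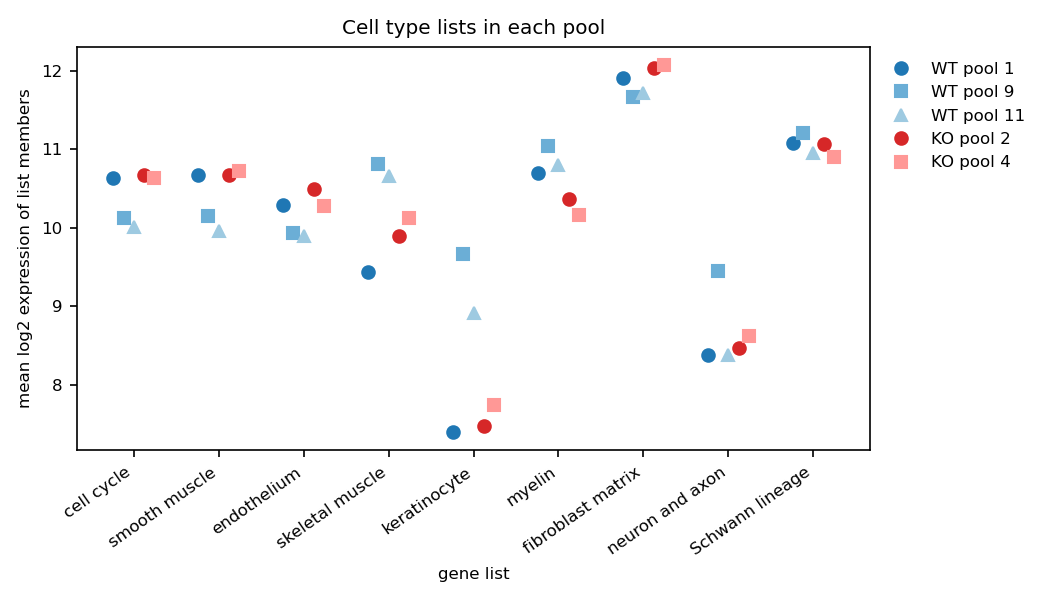
Mean log2 level of selected gene lists in each of the 5 pools, 1 point per pool, with WT and KO in different colours and offsets along the horizontal axis only to separate the points. The keratinocyte and skeletal muscle lists are highest in WT pools 9 and 11, at 9.66 and 8.92 and at 10.80 and 10.66.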

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

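The fits with WT pools 9 and 11 as a block, or without them, were chosen after the data were seen; all other alternatives were planned. No paired analysis was possible because pool numbers are not shared between the genotypes. Limma's count of probe sets changed by genotype ranged from 0 to 105 when 1 pool was left out, against 70 with all: 6 without WT pool 1, 1 without WT pool 9, 105 without WT pool 11, 0 without KO pool 2 (2309 at unadjusted p below 0.05) and 0 without KO pool 4 (327). The lone KO pool was then assumed to vary like the WT pools. For genes changed by genotype (65) the range was 0 to 93, with 6, 1, 93, 0 and 0 in the same order. For genes past 1.5-fold and unadjusted p (455) it was 103 to 932, with 681, 170, 467, 932 and 103. For gene lists shifted by genotype (20) it was 5 to 18, with 16, 13, 18, 5 and 13. The log2 value in Ebf2 level by genotype ranged from -2.62 to -2.12, with limma's adjusted p from 6.42e-38 to 0.857 over all alternatives.

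Quantile normalisation and median centring each left 1 probe set and 1 gene changed by genotype, with prior degrees of freedom of 4.87 and 5.47 in place of 17.4. The filter above the 50th percentile called 287 probe sets and 276 genes, with 302 genes past 1.5-fold and unadjusted p and 13 gene lists shifted. The trended and robust prior called 574 probe sets and 540 genes, and array weights called 268 and 250. The trended and robust prior had infinite prior degrees of freedom and gave the lowest Ebf2 adjusted p in limma, 6.42e-38. The fit without WT pool 11, with 105 probe sets, also had infinite prior degrees of freedom. Such counts rest on the prior more than on the spread of each probe set. Of the 70 probe sets, 64 were among those called with the trended and robust prior and 67 with array weights. The filter above the 50th percentile had 47 of them among its calls, and it takes out probe sets of low mean signal before the test. No named gene that it left in lost its call. Adjusted p below 0.1 gave 200 probe sets. The mean over the probe sets of a gene gave 163 genes, with adjustment over genes. That fit left out probe sets without 1 symbol and had 23.5 prior degrees of freedom, while only 4 symbols had several probe sets to average. The ordinary t-test gave 0 probe sets (498 at unadjusted p below 0.05), with 3 residual degrees of freedom. As a block, WT pools 9 and 11 left 0 probe sets (286 at unadjusted p below 0.05) and 0 genes changed in limma, 120 genes past 1.5-fold and unadjusted p, and 7 lists shifted. Without these pools there were 0 probe sets (127), 0 genes, 69 genes past 1.5-fold and 7 lists. Ebf2 was then at -2.56 in both, and the fits had 3.63 and 1.49 prior degrees of freedom. Estimated correlation and directional fry gave 0 lists (0 and 4 at unadjusted p below 0.05).

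Against WT pool 1 alone, by either fit, the medians turned to 0.55 for the list skeletal muscle, 0.20 for keratinocyte, 0.11 for brown adipocyte, 0.12 for erythroid and -0.0005 for pericyte and smooth muscle; with 1 pool left out the list interferon response ranged from -0.14 (without KO pool 2) to 0.58 (without KO pool 4). The cause was not tested. Besides Ebf2, 29 named genes were called, and 29 of 29 lost their call under either fit against WT pool 1 alone, without either KO pool, without WT pool 9, and under both scalings. Signal over background was not analysed here.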

Other observations

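All tests in this part were chosen after the data were seen, as were the genes and gene families named in it.

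Other called genes, outside the 12 largest changes in each direction, were picked for what they encode, with no test for a shared theme. Tgfb2, for transforming growth factor beta 2, rose in the KO pools (log2 fold change 1.03, SE 0.21), as did Fgf5, a fibroblast growth factor gene (0.88, SE 0.19), the Wnt receptor gene Fzd4 (0.84, SE 0.19), the secreted Wnt modulator gene Sfrp4 (0.90, SE 0.20) and S1pr1, a receptor of sphingosine 1-phosphate (0.79, SE 0.18), each with 3 WT and 2 KO pools. These rises were over 1.5 times smaller against WT pool 1 alone, at 0.57 for Tgfb2, 0.51 for Fgf5, 0.48 for Fzd4, 0.53 for Sfrp4 and 0.51 for S1pr1. Angptl4, an inhibitor of lipoprotein lipase, fell (-0.96, SE 0.21), and so did the cytokine gene Il16 (-0.97, SE 0.21, with 8.92 in KO pool 2 and 8.15 in KO pool 4 against a WT mean of 9.51, so that KO pool 4 gave most of the fall), Thbd, for thrombomodulin (-0.76, SE 0.17), and Gria2, a glutamate receptor subunit gene (-0.79, SE 0.18). Limma's adjusted p was 0.0213 for Tgfb2 and 0.0498 for S1pr1, and these calls share the limits of the 70 probe sets.

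Small nucleolar RNA genes lay lower in the KO pools as a group, and microRNA genes by less. Of 41 measured small nucleolar RNA genes 37 were lower and 0 passed singly (median log2 fold change -0.34, camera adjusted p = 5.24e-11 over the 2 families, adjusted p = 0.124 with an estimated correlation). The median was -0.20 in KO pool 2 and -0.52 in KO pool 4 relative to the WT mean, -0.25 against WT pool 1 alone, and -0.28 and -0.40 after median centring and quantile normalisation. Of 134 microRNA genes 89 were lower and 1, Mir379, fell (median -0.09, camera adjusted p = 8.22e-05, adjusted p = 0.0721 with an estimated correlation), with 76 and 78 lower and medians of -0.03 and -0.05 after the same 2 scalings. Whole-transcript probes on such genes can also read host gene or precursor RNA, which was not tested.

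The 5 pools can be split into 3 and 2 in 10 ways, too few for a share under 0.05. The real split called 70 probe sets, and 2 of the 10 splits, the real one included, called as many, with 292 as the highest of the others. The split with 292 sets WT pools 9 and 11 against the other 3 pools and points to a structure of the samples other than genotype. With these 2 pools as a block the genotypes are compared through WT pool 1 alone, so calls in that fit cannot separate this structure from genotype. The median absolute log2 fold change of the 65 called genes was 0.75 there, against 0.99 with all WT pools.

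The separation of WT pools 9 and 11 was set against 3 explanations. Genotype was not tested apart from the pattern, since the smaller SD of the difference of WT pool 1 from KO pool 2 (0.203) than from the nearest WT pool (0.319) is the pattern itself. The share of male pups did not follow the separation, as 3 of 3 Y-linked genes had values in pools 9 and 11 inside the range of the other 3 pools. That range was wide, with WT pool 1 lowest and KO pool 2 highest at all of them, so a part played by sex stays open. Added skin and muscle RNA that dilutes all other tissue alike was argued against by smooth muscle genes, which lay lower in pools 9 and 11 than Schwann lineage genes did by a difference of -0.70 (SE over pools 0.10, with the grouping of pools itself taken from the data). Skin and muscle genes were nevertheless higher there, so a different dissection or different litters may be part of the separation, and neither could be tested.

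The lower level of myelin genes was set against 2 explanations. A lower share of Schwann cells as the whole cause was set against 13 lineage genes outside the list (8 of them members of other fixed lists). The myelin mean minus the lineage mean was -0.38, -0.17 and -0.15 in WT pools 1, 9 and 11. In KO pools 2 and 4 it was -0.70 and -0.74, a difference of -0.49 (SE over pools 0.09). The lineage genes did not move alike, from -0.56 (Cdh19) and -0.47 (Erbb3) to 0.33 (L1cam) and 0.47 (Gfra3). Their mean is thus no neutral measure of the share of Schwann cells, and the gap does not decide the point. The separation of WT pools 9 and 11 stays open, because WT pool 1 is then the whole WT arm, against which the mean of all 15 measured myelin genes was -0.43 with no error between WT pools. Of the 5 called genes, whose direction there is fixed by the lack of overlap, the median was -1.02 (median SE 0.20) against all WT pools. It was -0.79 (median SE 0.27) against WT pool 1 alone. Their differences were smaller there, the SEs larger and the prior degrees of freedom fewer. Which of these ended their calls was not tested. An effect of genotype on myelin genes is thus a hypothesis that may hold. A delay in development and the filter on spread were untested. The share of Schwann cells and the makeup of the pools stay open, as Erbb3 and Cdh19 were lower in KO pool 4 (11.90 and 11.22) than in KO pool 2 (12.53 and 11.95).

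Some called genes lie next to each other. In the gene order of assembly GRCm38.p6, 3 pairs of adjacent measured genes were called in the same direction: Pi15 and Crispld1 on chromosome 1 (1.82 and 0.77), Kera and Epyc on chromosome 10 (1.99 and 1.80), and Sstr4 and Thbd on chromosome 2 (-0.75 and -0.76). Random sets of called genes held 0.21 such pairs on average, with a permutation p of 0.0011 in 10000 draws (one-sided), which argues against chance placement. Linkage to the targeted allele does not account for them, as 0 of the 3 pairs lie on chromosome 14 with Ebf2. There 19% of the 100 nearest measured genes were at unadjusted p below 0.05 against 14.5% of the rest (one-sided Fisher's exact p = 0.13). Of these 100 genes 1 was called, Tnfrsf10b, the 25th nearest to Ebf2 (log2 fold change 0.95, SE 0.17, limma adjusted p = 0.0112). Linkage to the allele was not tested for Tnfrsf10b alone and stays open. Shared regulation of adjacent genes may be behind the pairs, while Pi15 with Crispld1 and Kera with Epyc are related in sequence and cross-hybridisation was not tested.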
